A study of Mus musculus with 342 samples.

How the data were processed

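Whole liver RNA of 342 male Collaborative Cross mice was profiled on Affymetrix HT MG-430 PM arrays after 3' IVT labelling, per the labels. The labels give each mouse's line, its treatment, a study pair number shared by 1 vehicle and 1 TAK-875 mouse, and the pair's number within its line (strain pair). Doses were 0 or 600 mg/kg by oral gavage, with liver taken 24 hours later. The 342 samples form 171 study pairs over 44 lines. The labels mention 1 further line, which is not analysed here.

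The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Power Tools, per the submitters' processing notes. RMA corrects background, normalizes arrays to a common distribution and summarises the probes of a set. Tool versions are not given in the sources used here. The table used has 16397 probe sets, and values run from 1.62 to 13.81. Array medians run from 5.40 to 6.22, so the arrays of this table do not share 1 distribution, and other scalings were tried. Scanner signals and signal over background were not used here, so no probe set was removed as undetected.

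Probe sets were named through the platform's gene table, with symbols updated through the RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probe sets, 13083 name 1 gene, 261 name several and 3053 name none. Only the first kind was used. Each of 9093 genes was represented by its probe set with the highest mean over all arrays. Of those probe sets, 349 are of a class that can bind unrelated transcripts and 611 of a class that can bind several transcripts of a family. For 21 genes, different probe sets were called in both directions. Of the 25 genes with the largest changes, 4 had several probe sets, and all of these had 1 direction. Ffar1 was not analysed here.

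The tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Tests used limma 3.58.1 in R 4.3.3, with eBayes variance trended on mean level, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. For the mean over lines, the TAK-875 minus vehicle difference was averaged in each line, and the 44 line values were tested against 0. Each mouse is a separate animal, and the line was the unit because mice of a line share a genotype. For the interaction, the 171 pair differences were fitted with 1 mean per line, and a moderated F test asked whether all lines were equal, with 127 residual degrees of freedom. The same fit gave the genes called within each line, so all lines share 1 estimate of spread per gene. Vehicle arrays were compared between lines by the same F test. The standard deviation between lines was estimated after the sampling variance within lines was subtracted.

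The 36 gene lists were PPARA targets, CAR and PXR targets, NRF2 targets, integrated stress response, unfolded protein response, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis, bile acid and organic anion transport, FXR and FGF15/19 axis, acute phase, cell cycle, p53 targets, AHR targets, gluconeogenesis and fasting, glucocorticoid targets, circadian clock, male-biased and female-biased liver genes, interferon-stimulated genes, mitochondrial respiratory chain, proteasome, complement and coagulation, markers of Kupffer cells, endothelium, stellate cells, cholangiocytes, neutrophils, T and NK cells, B cells, red blood cells, pancreas, adipose tissue and muscle, and pericentral and periportal hepatocyte genes. Of 903 list entries, 660 were measured. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list's genes move on balance in 1 direction, and its mixed form whether they change in either, and neither compares the list with other genes. Fry called 20 lists and its mixed form 27. List responses per line are means of the members, tested by 100000 permutations in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Correlations between lists left out members shared by the pair of lists. Figures were drawn with matplotlib 3.10.9.

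Named genes were the 15 largest rises and 10 largest falls with the same direction in at least 9 of 10 lines, up to 4 members per list, the 12 genes with the largest SD of response between lines, the 10 with the largest SD between lines among vehicle mice, 3 genes in each of the 3 lines with the most calls, and genes of bile acid handling whatever their result. Ties put 5 lines among those with the fewest calls.

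The study pairs were taken as pairs because the labels say mice were treated in matched pairs. As a check, deviations of same-numbered arrays from their group means correlated by 0.0361 on average, against -0.0117 for arrays of different pairs in a line, and 60 of 171 pairs exceeded 0.1. The alternatives tried were the mean of all probe sets or every probe set, arrays centred on their medians, quantile normalization again, the dimmest 25% of genes left out, no variance trend, a threshold of 0.01, each strain pair number or line left out, array weights, the study pair as a block or no block, lines fitted alone, the median of a list, and other pairs for baseline and response. Added after the data were seen were robust regression, removal of pairs with a dim array, removal of pairs with a poorly correlated array, and an axis of array quality as a covariate. The axis is the first principal component of vehicle arrays after line means were removed, and holds 22.1% of that variance. Its scores correlated with the array mean by 0.614. Hsp90aa1, Malat1 and Cd2ap had the highest weights and Gm5165 and Zc3h3 the lowest. The clock gene Nr1d2 (0.0278) also lay near the high end, and Aacs (-0.0154), of fatty acid and triglyceride synthesis, near the low end. Whether the axis holds array quality alone, or also biology of the mice, was not tested. Dim arrays were those with a mean more than 4 median absolute deviations under the median of 6.33, namely vehicle arrays of CC039/Unc (5.94) and CC033/GeniUnc (5.98). Poorly correlated arrays were 7 TAK-875 arrays whose correlation with the others of their line and treatment lay under 0.91, a limit set after the values were seen; the next lowest was 0.916.

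The fits were tested on simulated data with 200 changed genes among 9093. Each gene was drawn as independent noise with its own spread, so variation shared between genes, such as the axis above, was absent. That spread was the same in every simulated line. In the real data the median spread of pair differences ran from 0.217 in CC061/GeniUnc to 0.483 in CC004/TauUnc, so calls in lines of unequal spread were not tested. The numbers of unchanged genes called below therefore need not hold for the real arrays. For the mean over lines, 61% of genes changed by 0.15 and 100% of genes changed by 0.3 (log2) were called, with 10 unchanged genes. For the interaction, 97.5% of genes with an SD of 0.5 between lines were called, with 7 unchanged genes, and for vehicle lines 100%, with 8. Within a line, 96% of genes changed by 1.5 were called, with 14 unchanged genes. Genomic positions are not given, because no genome of a build named by the files was used.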

Results

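Liver transcript levels were measured in male mice of 44 Collaborative Cross lines, a panel of recombinant inbred mouse lines bred from genetically diverse founders. Each mouse received 1 oral dose of either the methylcellulose vehicle or TAK-875 (fasiglifam) at 600 mg/kg, and its liver was taken 24 hours later. The sample labels and the design name TAK-875, while the title of the series gives another compound number, and the labels were followed. TAK-875 is an agonist of the free fatty acid receptor GPR40, developed for type 2 diabetes and withdrawn from development over liver injury. The mice were treated in matched pairs of the same line, with 1 vehicle mouse and 1 TAK-875 mouse in each of 171 study pairs. There were 4 pairs in 39 lines and 3 pairs in 5 lines. Each mouse gave 1 array, so 342 arrays entered the comparisons, 171 per treatment. The number of arrays, not a read depth, limits the precision. Array medians lay between 5.40 and 6.22 on the log2 scale. The median correlation of an array with the others of its line and treatment was 0.974, and the lowest was 0.817. In all, 9093 genes were tested, each through 1 probe set. No result is given for Ffar1, the gene of GPR40, because 0 of the probe sets used named it.

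The first comparison asked how the liver responded to TAK-875 on average over the 44 lines. Acot1, a cytosolic acyl-CoA thioesterase, was 2.59-fold higher with TAK-875, a log2 change of 1.37 ± 0.85 (SD over lines, n = 44), and higher in 41 lines. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, rose 1.76-fold (log2 0.81 ± 0.35, n = 44) and was higher in all 44 lines. The strongest fall was that of Dio1, the type 1 deiodinase that converts thyroxine to its active form, which was 2.31-fold lower (log2 -1.21 ± 0.55, n = 44) and lower in all 44 lines. Dbp, a transcription factor driven by the circadian clock, rose 2.49-fold (log2 1.32 ± 1.15, n = 44) and was higher in 40 lines. The limma adjusted p values were 1.5e-12 for Acot1, 5.7e-17 for Ehhadh, 1.9e-16 for Dio1 and 1.2e-08 for Dbp.

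By limma on the line mean differences, 2466 of the 9093 genes (27.1%) passed an adjusted p of 0.05. Of these, 1388 rose and 1078 fell, so that 56.3% of the genes called were higher with TAK-875. This balance depended on the scaling of the arrays: with each array centred on its median 1052 rose and 1334 fell (44.1% higher), and with quantile normalization applied again 1177 rose and 1383 fell (46.0% higher). Most changes were small, with a median size of 0.14 on the log2 scale. A change of at least 1.5-fold was seen for 23 of the genes called, of which 16 rose and 7 fell, and 5 genes changed at least 2-fold. The direction was shared by at least 40 of the 44 lines for 145 genes, and by every line for 6 genes, namely Ehhadh, Pctp, Acaa1b, Eci1, Dio1 and Pipox. Leaving out 1 pair turned the sign in at least 1 line for each of the 6 (1 line for Ehhadh, Pctp and Dio1, 2 for Eci1, 4 for Acaa1b, 6 for Pipox). Eci1 and Pipox were singled out after their values were seen.

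Other genes that rose in at least 40 lines included the acyl-CoA thioesterases Acot3 (log2 1.15 ± 0.94) and Acot2 (0.61 ± 0.46), and 2010003K11Rik (1.07 ± 0.79). Acot1, Acot2 and Acot3 are close paralogs, and the probe set of Acot3 is of a class that can bind several transcripts of a family, so their separate levels are uncertain. Vnn1, a pantetheinase, rose by 0.98 ± 0.63, and Pctp, a phosphatidylcholine transfer protein, by 0.88 ± 0.50. Chrna2, a nicotinic receptor subunit, rose by 0.82 ± 0.54. The fatty aldehyde dehydrogenase Aldh3a2 (0.64 ± 0.37), the glutathione transferase Gstt2 (0.62 ± 0.33), the phosphate transporter Slc20a1 (0.61 ± 0.52), the peroxisomal thiolase Acaa1b (0.59 ± 0.32), the retinol dehydrogenase Rdh9 (0.57 ± 0.47) and the deubiquitinase Usp2 (0.56 ± 0.52) rose less. Among genes that fell were the organic anion transporter Slc22a7 (-0.84 ± 0.62), the corticosteroid-binding globulin Serpina6 (-0.66 ± 0.45) and the clock transcription factor Npas2 (-0.66 ± 0.57). The dicarboxylate transporter Slc13a3 (-0.63 ± 0.38), liver pyruvate kinase Pklr (-0.58 ± 0.40) and C730049O14Rik (-0.56 ± 0.40) also fell. Cela1 (-0.56 ± 0.47), Tmie (-0.55 ± 0.45, from a probe set that can bind unrelated transcripts) and the mitochondrial carrier Slc25a23 (-0.53 ± 0.30) completed the 10 largest falls shared by at least 40 lines.

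**Figure D1:**
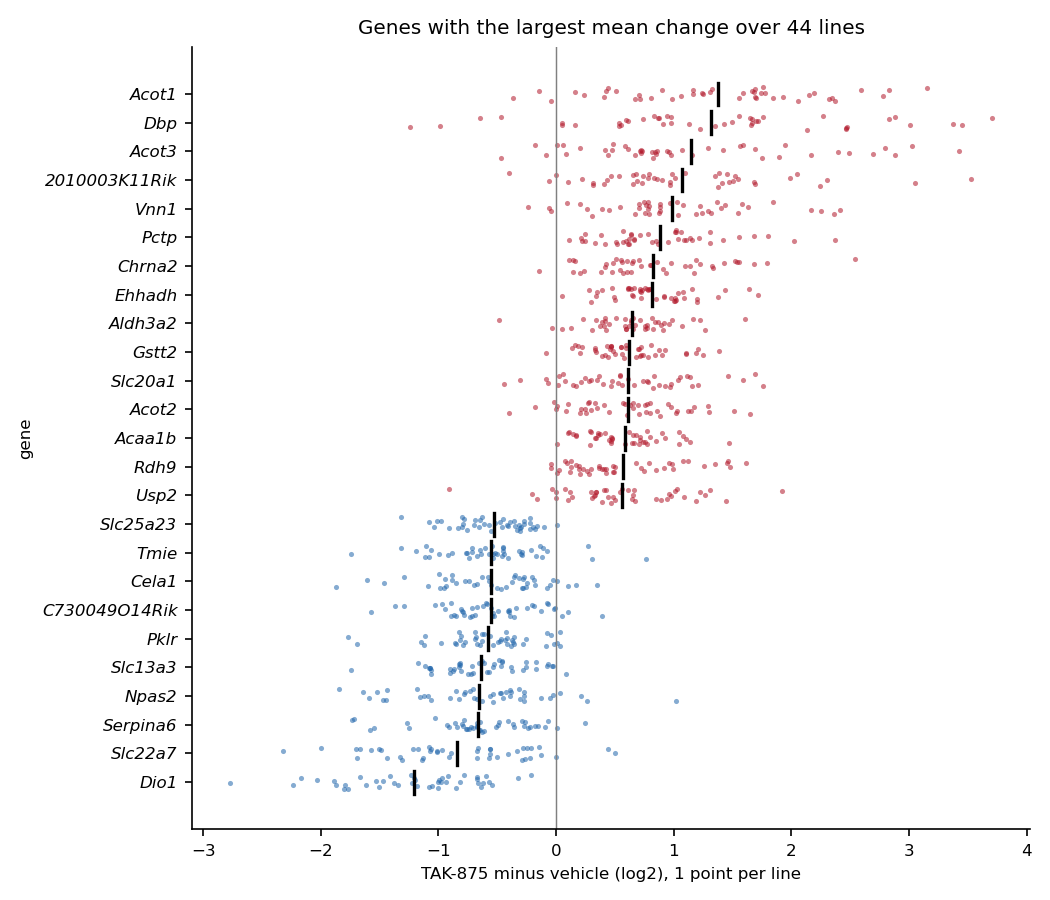
Change with TAK-875 against vehicle (log2, x axis) of the 15 genes with the largest rise and the 10 with the largest fall shared by at least 40 of 44 lines. Each point is the mean difference of 1 line, red for genes that rose and blue for genes that fell, and the black bar is the mean over lines; Dio1 lay below 0 and Ehhadh, Pctp and Acaa1b above 0 in all 44 lines.

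Among 4 genes of bile acid handling that were to be reported whatever their result, Abcc2, the canalicular organic anion pump, rose by 0.21 ± 0.31 (limma adjusted p = 2.8e-04, higher in 34 of 44 lines). The bile salt export pump Abcb11 changed by -0.07 ± 0.50 (limma adjusted p = 0.505), less than its spread between lines. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.18 ± 1.14 (adjusted p = 0.451), and the bile acid uptake transporter Slc10a1 at -0.06 ± 0.19 (adjusted p = 0.128). Slc10a1 passed the threshold in 4 of the alternatives, among them centred arrays (log2 -0.07, adjusted p = 0.0265).

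Of 36 gene lists, 35 had enough measured members for a test, and 14 of these passed with limma's camera at its preset correlation of 0.01, 5 higher and 9 lower with TAK-875. With an estimated correlation 5 of them held: PPARA targets, proteasome, complement and coagulation, periportal hepatocyte genes and B cell markers. Of 37 measured targets of PPARA, the nuclear receptor that induces fatty acid oxidation, 31 rose, 1 fell and 5 did not pass. Adjusted over the list alone, 32 rose and 1 fell. The list mean rose by 0.36 ± 0.20 (SD over lines, n = 44) and was above 0 in 43 lines (camera adjusted p = 5.9e-26, and adjusted p = 0.00712 with an estimated correlation). It was 0.33 without 7 pairs whose TAK-875 arrays correlated poorly with the others of their line (adjusted p = 1.3e-21). Besides the genes above, Slc22a5, the carnitine transporter, rose by 0.49, Cyp4a10 by 0.45 and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, by 0.34. The member that fell was Me1, malic enzyme, at -0.26. These 4 were chosen after their values were seen. Of 28 proteasome genes, 24 rose and 0 fell (25 and 0 adjusted over the list alone). Psmb4 rose by 0.25 ± 0.13, Psmb5 by 0.21 ± 0.24 and Psmc4 by 0.21 ± 0.20, and the list mean rose by 0.14 ± 0.09 (camera adjusted p = 1.7e-17, and adjusted p = 0.00876 with an estimated correlation).

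Genes of complement and coagulation, secreted mainly by hepatocytes, fell: 19 of 34 fell and 0 rose (21 and 0 adjusted over the list alone). C2 fell by 0.32, C9 by 0.31, Mbl2 by 0.29 and the coagulation factor F7 by 0.28 on the log2 scale (camera adjusted p = 4.7e-12, and adjusted p = 0.0367 with an estimated correlation). Of 15 genes typical of periportal hepatocytes, 10 fell and 1 rose, and the counts were 10 and 1 adjusted over the list alone. Ctsc, a lysosomal protease, was at -0.38, Aldh1b1 at -0.24 and Hal, histidine ammonia-lyase, at -0.21, while Hsd17b13 was at 0.18 (camera adjusted p = 1.2e-05, and adjusted p = 0.0414 with an estimated correlation). Of 16 pericentral hepatocyte genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone), with Aldh3a2 at 0.64, Nr1i3, the nuclear receptor CAR, at 0.40, Slc1a2 at -0.27 and Gulo at -0.25. That list as a whole did not pass (camera adjusted p = 0.165).

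Markers of several other cell types of the liver fell in the same samples. Of 14 Kupffer cell and macrophage markers, 11 fell and 0 rose (11 and 0 adjusted over the list alone). Mpeg1 fell by 0.52, Cd5l by 0.30 and Clec4f by 0.28, and the list mean was -0.19 ± 0.23 (camera adjusted p = 7.1e-08, but adjusted p = 0.111 with an estimated correlation). Of 14 liver endothelial markers, 5 fell and 0 rose (8 and 1 adjusted over the list alone), with Stab2 at -0.26 and Dnase1l3 at -0.24 (camera adjusted p = 0.00169, but adjusted p = 0.143 with an estimated correlation). Of 12 stellate cell and fibroblast markers, 3 fell and 0 rose (3 and 0 adjusted over the list alone): Col3a1 at -0.29, Colec11 at -0.15 and Bgn at -0.12 (camera adjusted p = 0.00814, but adjusted p = 0.177 with an estimated correlation). Of 6 B cell markers, 4 fell and 0 rose (4 and 0 adjusted over the list alone). Of these 4, H2-Ab1 (-0.49), Cd74 (-0.36) and H2-Aa (-0.35) belong to antigen presentation on MHC class II, which macrophages also carry, and Jchain (-0.14) is an antibody component (camera adjusted p = 3.8e-05, and adjusted p = 0.00712 with an estimated correlation).

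The remaining marker lists did not pass by camera, though red blood cell and pancreas markers passed by fry. Of 4 cholangiocyte and 7 neutrophil markers, 0 passed by limma, and 0 of either list had an unadjusted p under 0.05. Their camera adjusted p values were 0.978 and 0.931. The neutrophil marker S100a9 was at -0.05, but passed at -0.15 without the 7 poorly correlated pairs (limma adjusted p = 0.0345). The single T and NK cell marker measured, Cd3e, was at -0.01 and was not tested as a list. Of 4 red blood cell markers 2 fell, Alas2 at -0.19 and Hbb-b2 at -0.15 (camera adjusted p = 0.0642). Hbb-b2 was at -0.12 without strain pair number 2 and at -0.09 without number 4, and passed in neither (limma adjusted p = 0.143 and 0.267). Of 6 pancreas markers 1 fell, Cela1 (camera adjusted p = 0.196). Of 3 adipose markers 1 rose, Lipe at 0.12 (0.620), and of 7 muscle markers 1 rose, Mylpf at 0.12 (0.931). Counts adjusted over the list alone were the same for all of these marker lists. The muscle list's mean was 0.01 as deposited and -0.0040 with centred arrays, and neither Lipe nor Mylpf passed with centred arrays.

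Of 19 circadian clock genes, 12 rose and 4 fell (12 and 4 adjusted over the list alone). The clock output genes Dbp, Tef (0.56 ± 0.40), Usp2 and Ciart (0.56) rose, and so did Per2 (0.46), whereas Npas2, Arntl (-0.53) and Nfil3 (-0.49) fell. Ciart, Per2, Arntl and Nfil3 were chosen after their values were seen. The list was higher as a whole (camera adjusted p = 0.00835, but adjusted p = 0.143 with an estimated correlation and 0.0557 without the 7 poorly correlated pairs). Of 29 genes of the unfolded protein response, 15 rose and 0 fell (15 and 0 adjusted over the list alone), among them Derl3 (0.84 ± 0.81), Creld2 (0.40 ± 0.53) and Sdf2l1 (0.31 ± 0.39), which act in protein quality control of the endoplasmic reticulum (camera adjusted p = 1.9e-04, but adjusted p = 0.260 with an estimated correlation). Of 16 cholesterol synthesis genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone). Mvd rose by 0.51 ± 0.86, Hsd17b7 by 0.51 ± 0.47 and Msmo1 by 0.41 ± 0.58 (camera adjusted p = 0.00140, but adjusted p = 0.465 with an estimated correlation). Without strain pair number 2, Mvd was at 0.37 and did not pass (limma adjusted p = 0.0718).

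Of 52 genes of the mitochondrial respiratory chain, 26 fell and 0 rose (31 and 0 adjusted over the list alone). The falls were small: Sdha fell by 0.15, Ndufa9 by 0.14 and Ndufs8 by 0.13, and the list mean was -0.05 ± 0.05 (camera adjusted p = 1.1e-09, but adjusted p = 0.109 with an estimated correlation). Of 18 male-biased liver genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone), with Elovl3 at -0.53, Hsd3b5 at -0.49 and Bcl6 at -0.46 (camera adjusted p = 1.9e-04, but adjusted p = 0.143 with an estimated correlation). Of 20 female-biased liver genes, 3 rose and 0 fell, also when adjusted over the list alone: Acot3, Trim24 at 0.29 and Sult1e1 at 0.22 (camera adjusted p = 0.445). Of 18 interferon-stimulated genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone), among them Rtp4 at -0.34 and Irf7 at -0.27 (camera adjusted p = 0.00224, but adjusted p = 0.363 with an estimated correlation).

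In the other response lists the members called went both ways or were few, and no list passed as a whole by camera on the line mean differences of all pairs at its preset correlation with 1 probe set per gene. By fry, NRF2 targets, the FXR and FGF15/19 axis, AHR targets, and gluconeogenesis and fasting passed. Of 29 targets of CAR and PXR, the receptors that induce drug metabolism, 6 rose and 5 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.931). Alas1 was at 0.59, Abcc3 at 0.50, Gadd45b at 0.47 and Sult5a1 at -0.51. Of 30 targets of NRF2, the regulator of antioxidant genes, 9 rose and 6 fell (10 and 7 adjusted over the list alone). Nqo1 was at 0.51, Ephx1 at 0.39 and Osgin1 at -0.40 (camera adjusted p = 0.165, and 0.0386 with the study pair as a block, where the pair and not the line was the unit). Of 32 genes of the integrated stress response, 7 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.796), with Fgf21 at 0.46, Psat1 at 0.34 and Atf3 at 0.33. Without strain pair number 4, Atf3 was at 0.17 and did not pass (limma adjusted p = 0.110). Of 26 genes of fatty acid and triglyceride synthesis, 2 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.0675), with Pklr at -0.58, Elovl3 at -0.53 and Aacs at 0.40. Of 17 genes of gluconeogenesis and fasting, 2 rose and 7 fell (2 and 7 adjusted over the list alone). G6pc, the last enzyme of glucose release, was at -0.50, Tat at 0.17 and Asl at -0.16 (camera adjusted p = 0.0502, but 0.0363 with the study pair as the block and the unit, 0.0405 with the mean of all probe sets and 0.0109 without the 7 poorly correlated pairs).

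Of 20 bile acid synthesis genes, 4 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.470). Cyp8b1, the sterol 12-hydroxylase, was at -0.61, Cyp46a1 and Cyp2c70 each at -0.30 and Acot8 at 0.30. Of 18 bile acid and organic anion transporters, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.982). Abcc3, a basolateral export pump, was at 0.50 ± 0.29, Abcb4, the canalicular phospholipid transporter, at 0.33 ± 0.34 and Slco1a1 at -0.25 ± 0.58. Of 14 genes of the FXR and FGF15/19 axis, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.214). Nr0b2, a target of FXR, was at -0.18. Of 30 acute phase genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0675, and 0.00334 without the 7 poorly correlated pairs), with Saa3 at -0.69, Cd14 at 0.48 and Hamp2 at -0.33. Without strain pair number 4, Cd14 was at 0.31 and did not pass (limma adjusted p = 0.0683). Hamp2 did not pass without number 1 or without number 2 (limma adjusted p = 0.0938 and 0.0522). Of 22 cell cycle genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.978). Ccnd1 was at 0.38, Mcm6 at 0.22 and Tk1 at -0.28, and the list's mean was 0.02 while its median was -0.02. Of 19 p53 targets 1 rose and 0 fell, also when adjusted over the list alone: Ccng1 was at 0.16 (camera adjusted p = 0.817), and it did not pass with the mean of its probe sets (adjusted p = 0.213). Of 7 AHR targets, 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.470), with Nqo1 at 0.51, Cyp1a1 at 0.23 and Cyp1a2 at -0.20. Of 16 glucocorticoid targets, 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.925), with Fkbp5 at 0.36, Per1 at 0.33 and Dusp1 at -0.22.

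The second comparison asked which responses to TAK-875 differed between lines. Egr1, an immediate early transcription factor, ranged from a mean of -3.79 ± 1.42 (SD, n = 4 pairs) in CC063/Unc to 3.62 ± 3.02 (n = 4) in CC029/Unc. The acute phase gene Orm2 ranged from -2.75 ± 1.07 (n = 3) in CC065/Unc to 4.01 ± 0.75 (n = 3) in CC053/Unc, and its neighbour in the same family, Orm3, from -3.19 ± 1.04 to 3.95 ± 1.30 in the same lines. Cyp7a1 was at -2.15 ± 0.97 (n = 3) in CC042/GeniUnc and at 2.74 ± 0.60 (n = 4) in CC040/TauUnc. Acot1 ranged from -0.36 ± 0.53 (n = 4) in CC019/TauUnc to 3.16 ± 0.71 (n = 4) in CC070/TauUnc, and the lower end was -0.20 without study pair 60.

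By limma's F test on the pair differences, the response of 1474 genes (16.2%) differed between lines, and 438 of these were also called in the mean over lines. The standard deviation of the response between lines, after the sampling variance within lines was taken off, was largest for Egr1 (0.96), Dbp (0.82), Orm3 (0.79), Orm2 (0.77), Cyp7a1 (0.75) and Mfsd2a (0.70), a lysophospholipid transporter. It was 0.64 for Acot3 and for the cell cycle inhibitor Cdkn1a, 0.62 for 2010003K11Rik, 0.58 for the anion transporter Slco1a4 and the receptor kinase Grk5, and 0.58 for Acot1. Of these 12 genes, Grk5 had the smallest adjusted p (1.6e-04) and Cdkn1a the largest (0.0450). The count of 1474 moved by more than 1.5 times when a strain pair number was left out: it was 240 without number 1, 138 without number 2, 129 without number 3 and 691 without number 4. It was 610 with an axis of array quality as a covariate, and Egr1, Dbp, Orm3, Orm2, Cyp7a1 and Cdkn1a lost their calls in a fit without the pairing. Sequence differences between lines under a probe, which can alter how far its signal responds, were not measured, so some of the 1474 genes can owe their call to them. No array batch entered the fit. A batch shared by 1 treatment arm of a line cannot be told apart here from a line by treatment effect. The axis score differed in 1 direction in all 4 pairs of CC041/TauUnc (-42.6, -46.3, -74.8 and -35.2) and of CC005/TauUnc (69.7, 56.8, 24.1 and 12.1).

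As a mean over the 37 PPARA targets, the response ranged from -0.04 in CC019/TauUnc (-0.06 to -0.02 with 1 pair left out) to 0.66 in CC053/Unc, where the 3 pairs were at 0.42, 1.13 and 0.43. Without study pair 178, whose TAK-875 array correlated with the others of its line and treatment by only 0.892, CC053/Unc was at 0.43, and the highest line was CC059/TauUnc at 0.64. In CC019/TauUnc the TAK-875 array had a lower median than its vehicle array in study pairs 57 (5.70 against 5.96), 58 (5.77 against 5.99) and 60 (5.99 against 6.04). In pair 59 it was higher (6.01 against 5.96). Line values with centred arrays are not given here, so the place of this line as the lowest may depend on array scaling. The difference between lines did not pass after adjustment over 35 lists (permutation p = 0.0109, adjusted p = 0.0651), but did without the 7 poorly correlated pairs (adjusted p = 0.0192). Those arrays were picked for departing from others of their line and treatment. Their removal tends to lower the spread within lines, so this pass cannot decide whether the lines differ. With all pairs, bile acid and organic anion transporters (SD between lines 0.13), p53 targets (0.10), AHR targets (0.10) and periportal hepatocyte genes (0.07) passed, each with a permutation adjusted p of 0.0402. None of these 4 lists passed when the median of the members was used in place of the mean, and leaving out 1 strain pair number left 0 or 1 list past the threshold.

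**Figure D2:**
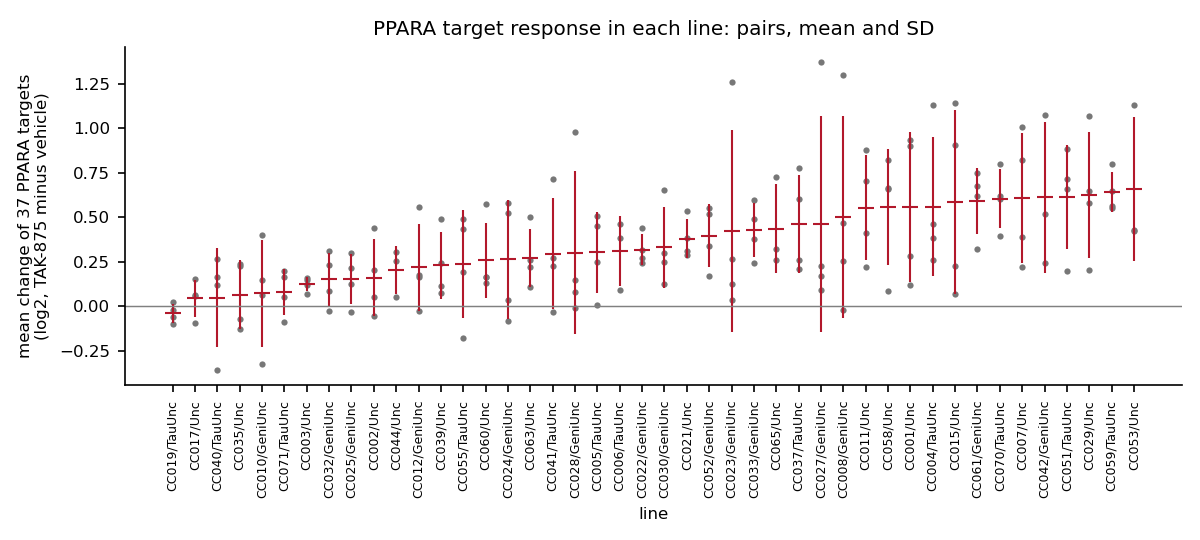
Mean change of 37 PPARA targets (log2, TAK-875 minus vehicle, y axis) in each of 44 lines (x axis, sorted by mean). Grey points are study pairs and red bars the line mean with its SD. With arrays as deposited, line means run from -0.04 in CC019/TauUnc to 0.66 in CC053/Unc, which is at 0.43 without study pair 178, below CC059/TauUnc at 0.64.

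Over the 44 lines, 28 correlations between the mean responses of 8 lists were computed. The responses of PPARA targets and of CAR and PXR targets were positively correlated (Pearson r = 0.446, permutation p = 0.00222, adjusted p = 0.0311; Spearman rho = 0.349, permutation p = 0.0203, adjusted p = 0.113; r = 0.411 without the 2 lines farthest from the median). The integrated stress response and bile acid synthesis were negatively correlated (r = -0.474, permutation p = 0.00106, adjusted p = 0.0297; rho = -0.554, permutation p = 1.2e-04, adjusted p = 0.00336; r = -0.448 without 2 lines). When 1 list was taken from strain pairs 1 and 2 and the other from pairs 3 and 4, r was 0.119 and 0.284 for the first relation and -0.277 and -0.176 for the second. With that split 0 of the 28 relations passed, and neither of these relations did with centred arrays or without the 7 poorly correlated pairs (adjusted p = 0.0707 for both).

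For the same 8 lists, the vehicle level in some pairs was set against the response in other pairs of the line, and 0 of 8 relations passed in either arrangement of the pairs. By permutation, 2 of the 8 had an unadjusted p under 0.05. CAR and PXR targets gave r = -0.318 (permutation p = 0.0353, adjusted p = 0.159; rho = -0.255, permutation p = 0.0956, adjusted p = 0.382; r = -0.210 without 2 lines). Bile acid synthesis gave r = -0.312 (permutation p = 0.0398, adjusted p = 0.159; rho = -0.339, permutation p = 0.0250, adjusted p = 0.1999; r = -0.373 without 2 lines).

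The third comparison asked how far each line responded on its own. CC041/TauUnc had the most genes called, 1403, with Dbp at 3.45 ± 0.56 (SD, n = 4 pairs), the cytoskeletal adaptor Sorbs2 at -2.15 ± 0.56 and Rnf170 at -1.96 ± 0.41. CC005/TauUnc had 1031, with Vnn1 at 2.36 ± 1.17, Txlng at 1.88 ± 1.96 and the crystallin Crybb3 at -1.79 ± 1.45 (n = 4). CC052/GeniUnc had 1028, with 2010003K11Rik at 3.53 ± 1.46, the methyltransferase Inmt at -3.00 ± 2.83 and Trim16 at -2.71 ± 2.70 (n = 4). Txlng was higher in 3 of the 4 pairs and Inmt lower in 3 of 4, and the other 7 genes had 1 direction in all 4 pairs of their line. At the other end, CC024/GeniUnc, CC032/GeniUnc and CC040/TauUnc had 1 gene each, and CC003/Unc and CC035/Unc had 0 by limma. In the latter lines 346 and 429 genes had an unadjusted limma p under 0.05. Each number is below a share of 0.05 of the 9093 genes tested, the share that no response would give on average. The order of these lines moved when a strain pair number was left out. CC032/GeniUnc had 5 genes without number 2, CC035/Unc 4 without number 3 and CC003/Unc 3 without number 1. CC024/GeniUnc and CC040/TauUnc had 0 without number 1.

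The median was 28 genes per line, 42 lines had at least 1 call and 12 lines at least 100. Whether lines differed was tested only by the interaction above. These counts depended on the axis of array quality, which may also hold biology of the mice. With the axis as a covariate, CC041/TauUnc had 1 gene called, CC005/TauUnc 69 and CC052/GeniUnc 1362. Sorbs2 was then at -1.04 and Txlng at 0.73, and neither passed, nor did Rnf170 at -0.53. Dbp at 3.14 and Crybb3 at -1.69 also missed the threshold, though their changes moved little. Leaving out strain pair number 3 took CC041/TauUnc to 28 genes and CC052/GeniUnc to 188, and leaving out number 1 took CC005/TauUnc to 31. Inmt was at -1.80 without number 1 (adjusted p = 0.0755), Trim16 at -1.87 without number 3 (0.138) and Txlng at 1.22 without number 2 (0.334), and none of these passed. Sorbs2, Rnf170 and Crybb3 also lost their calls without at least 1 number. With each line fitted alone the 3 lines had 2531, 234 and 4 genes, and the median was 0. With centred arrays CC052/GeniUnc had 674 genes. With the mean of its probe sets Rnf170 was at -0.06 in CC041/TauUnc and did not pass.

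**Figure D3:**
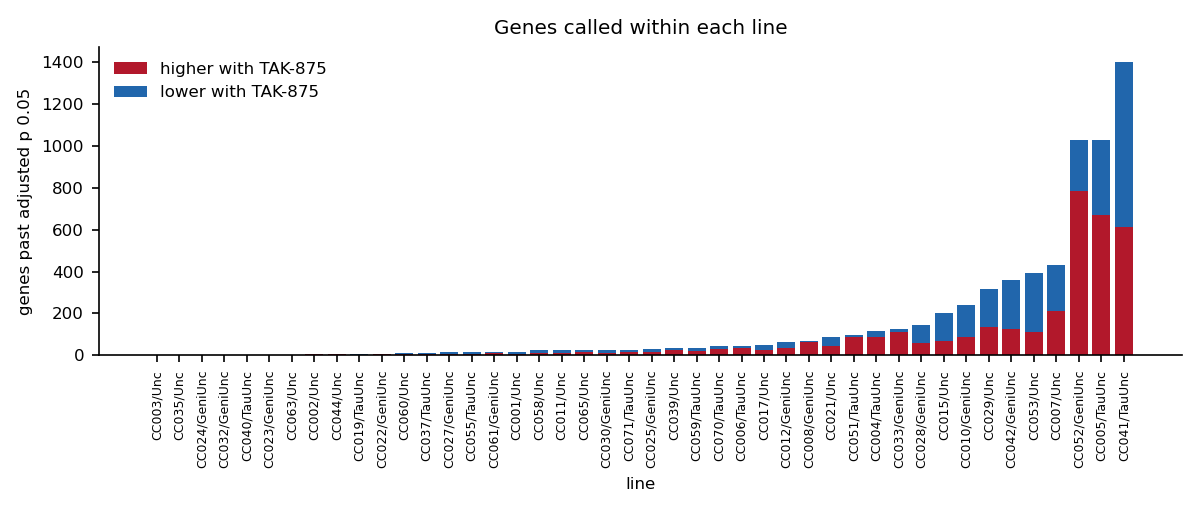
Number of genes past an adjusted p of 0.05 in each of 44 lines (x axis, sorted by the number), stacked as genes higher (red) and lower (blue) with TAK-875. The numbers run from 0 in CC003/Unc and CC035/Unc to 1403 in CC041/TauUnc, with a median of 28.

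The fourth comparison asked how the lines differed in the vehicle mice. Ugt3a2, a UDP-glycosyltransferase, had the largest spread between lines, an SD of 3.48 against 0.59 within lines, from 3.64 in CC003/Unc to 11.64 in CC042/GeniUnc. Obp2a, an odorant-binding protein, had an SD of 3.13 and the sulfotransferase Sult3a1 an SD of 2.72, the latter with 1.20 within lines. The carboxylesterase Ces2b (2.51), the aldo-keto reductase Akr1c18 (2.40), Wfdc21 (2.18) and Gm4788 (2.14) followed. The cholesterol 24-hydroxylase Cyp46a1 had an SD of 2.12, the cytochrome P450 Cyp2c39 of 2.01 and the glycosyltransferase B4galnt1 of 2.00. By limma's F test 8908 of the 9093 genes (98.0%) differed between lines, 161 of them with an SD of at least 1, and in the median gene 43.3% of the variance lay between lines. Sequence differences between lines under a probe also change its signal, and they were not measured. Study pair numbers run in sequence within a line, and no day of treatment or array batch entered the fit. Line therefore cannot be told apart here from a batch shared by the mice of a line. Among 37 genes with an SD of at least 1 and more than 1 probe set, the line means of a pair of probe sets correlated with a median r of 0.923 across lines. Over all 2875 genes with several probe sets the median r was 0.591, against 0.0531 for probe sets of different genes.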

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

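The test of whether markers of different cell types fell alike, the use of the array quality axis as a covariate, and the removal of poorly correlated arrays were chosen after the result was seen. The response to TAK-875 differed between lines for 1474 genes by limma's F test. The SD of the response between lines was 0.96 for Egr1, 0.82 for Dbp, 0.79 for Orm3, 0.77 for Orm2, 0.75 for Cyp7a1, 0.70 for Mfsd2a, 0.64 for Acot3, 0.64 for Cdkn1a, 0.62 for 2010003K11Rik, 0.58 for Slco1a4, 0.58 for Grk5 and 0.58 for Acot1. Among list means it was 0.131 for bile acid and organic anion transporters, 0.0978 for p53 targets, 0.0967 for AHR targets and 0.0733 for periportal hepatocyte genes. In the 24 groups of 4 pairs behind the genes named within lines and at the ends of the interaction, 0 single pairs stood apart by Dixon's test, where chance gives about 1.2.

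Other splits of the arrays were tried for each count. With vehicle and TAK-875 swapped at random within pairs, 1 of 100 splits, the real one, gave as many genes in the mean over lines as the 2466 found, and the highest other gave 1. Pair differences dealt to lines at random gave as many as 1474 interaction genes in 1 of 100, with a highest other of 3. The median of 28 genes per line was reached in 1 of 100 swaps (highest other 1), and the 8908 genes between vehicle lines in 1 of 100 deals of arrays to lines (highest other 8). A share of 1 in 100 is the smallest that 100 splits can give. Pairs or arrays were swapped or dealt independently, which breaks up shifts shared within a line, and whole lines were not swapped. Independent swaps or deals thus did not reach these 4 counts, but shifts shared within a line or treatment arm were not covered. For the vehicle mice, dealing arrays to lines cannot separate line from a batch shared by a line. Within a line there are 8 splits, too few for a share under 0.05. In CC041/TauUnc (1403 genes, highest other 0), CC005/TauUnc (1031, highest other 35) and CC052/GeniUnc (1028, highest other 754), 1 of the 8 splits, the real one, gave as many. The 754 genes in CC052/GeniUnc came with study pair 134 alone swapped, and in that pair Inmt (0.21) and Trim16 (-0.13) were near 0, while 2010003K11Rik was at 1.596; why this split calls so many genes was not tested. In CC003/Unc and CC035/Unc, with 0 genes, all 8 splits gave as many (highest other 2), and in CC024/GeniUnc, CC032/GeniUnc and CC040/TauUnc, with 1 gene, 2 of the 8 did (highest other 1).

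Clock genes changed with TAK-875, with Dbp up and Npas2 and Arntl down, but the list's call ended without 7 poorly correlated TAK-875 arrays (from 0.19, SD over lines 0.18, to 0.16, SD 0.15, camera adjusted p = 0.0557). The mean and its SD both fell, and why the call was lost was not tested. The list test asks for 1 direction, while members of this list went both ways. Dbp, Tef, Usp2 and Npas2 each kept their limma call without the 7 pairs. A shift of whole arrays is argued against, since the list mean with centred arrays was 0.171 against 0.19 as deposited. Centring moves every list by the same amount, so it cannot test effects that depend on signal level. With quantile normalization again the list mean was 0.171. A different time of day at collection stays open: over 18 clock genes other than Dbp, the changes followed those predicted from each gene's slope on Dbp among vehicle mice (r = 0.927 across genes, which are not independent replicates; 17 of 18 signs; rho = 0.831), and Dbp varied among vehicle mice of a line with an SD of 1.27. An effect of TAK-875 on the clock itself, or on feeding, may give the same pattern, was not tested, and also stays open, since collection times were not used here. Through Dbp the same slopes predict a change of -0.0057 for the PPARA list, against 0.355 observed.

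The number of genes called differed widely between lines. A larger spread between the pairs of a line would go with more calls if a few extreme pairs made them, and rho over lines was 0.414 (permutation p = 0.00556; r = 0.124, permutation p = 0.423; r = 0.124 without 2 lines), so this remains a candidate explanation. The median spread ran from 0.217 in CC061/GeniUnc to 0.483 in CC004/TauUnc. It was 0.270 in CC041/TauUnc, 0.350 in CC005/TauUnc and 0.440 in CC052/GeniUnc. A large spread was thus not seen in CC041/TauUnc, the line with the most calls. The size of the array quality difference gave rho = 0.239 (permutation p = 0.117; r = 0.451, permutation p = 0.00579; r = 0.262 without the 2 lines farthest from the median, so r rests partly on them), under the bound of 0.3 by less than its SE of 0.152, a margin asked for only after the value was seen, and stays open over all lines. As a covariate the axis left 1 gene in CC041/TauUnc and 69 in CC005/TauUnc (49 of them called before), where Sorbs2 moved from -2.15 (SE 0.44) to -1.04 (SE 0.34) and Txlng, itself among the genes with the highest weights on the axis, from 1.88 (SE 0.59) to 0.73 (SE 0.47), while Dbp in CC041/TauUnc moved only from 3.45 (SE 0.77) to 3.14 (SE 0.81) and lost its call (adjusted p = 0.0989), the adjustment being stricter where so few genes pass. In CC052/GeniUnc the count was 1362, with all 1028 genes kept, which argues against the axis there; a difference of genotype is untested for all 3 lines.

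With TAK-875, 11 of 14 Kupffer cell, 5 of 14 endothelial, 3 of 12 stellate cell and 4 of 6 B cell markers fell, and of these lists only that of B cells passed with an estimated correlation (adjusted p = 0.00712, against 0.143 for endothelium and 0.177 for stellate cells). A lower share of RNA from all cells other than hepatocytes would lower them alike if their markers were equally specific and equally far above background. The Kupffer cell mean fell below the mean of the endothelial and stellate lists by -0.107 (SE 0.0322, below 0 in 31 of 44 lines, permutation p = 9.0e-04). Specificity and background were not measured, so this difference cannot decide, and a lower share stays open. A shift of whole arrays is argued against by a Kupffer cell mean of -0.208 with centred arrays, against -0.19 as deposited. Centring cannot test effects that depend on signal level, and the mean was -0.208 with quantile normalization again. As a hypothesis, found and tested on the same data, macrophages may have become fewer or lost transcripts, which whole liver does not separate; of the markers with the highest array signal in vehicle mice, which does not rank their abundance, Cd5l (9.86) fell by 0.30, C1qa (8.33) by 0.21, Clec4f (8.15) by 0.28 and Mpeg1 (8.06) by 0.52. The list's adjusted p ran from 2.0e-08 without the 7 poorly correlated pairs to 0.111 with an estimated correlation, where it did not pass, so the fall of the list relative to other genes stays open too.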

How the results depend on the processing

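The fits with the axis of array quality, without dim arrays, without 7 pairs with a poorly correlated array and by robust regression were chosen after the data were seen. No named gene or list past its threshold reversed its direction in the alternatives that gave it a value. Directions of other genes were not followed, and with every probe set tested 21 genes were called both ways. The balance of calls did reverse: 56.3% rose as deposited, 44.1% with centred arrays and 46.0% with quantile normalization again. The 2466 genes of the mean over lines stayed within 1.5 times in every alternative (1657 to 3083; 2354 to 2581 with 1 line left out; 1926 to 2393 without 1 strain pair number), though at a threshold of 0.01 those that fell were 715. The 8908 genes between vehicle lines ranged from 6793, where fewer genes were tested, to 8990. Of the 1474 interaction genes, 333 passed a threshold of 0.01, 129 to 691 passed without 1 strain pair number, where fewer pairs entered, and 610 with the axis as covariate. All 12 named interaction genes lost their call in at least 1 alternative. The median of 28 genes per line was 7 at 0.01, 5 to 17.5 without 1 strain pair number, 0 with each line alone, 43.5 with the axis and 49.5 without the 7 pairs. The 12 lines with at least 100 genes were 5 at 0.01, 7 to 11 without 1 strain pair number and 3 with each line alone. Of 14 lists, 5 passed with an estimated correlation. Of 4 lists that differed between lines, 0 passed with the median of members and 0 to 1 without 1 strain pair number, but 7 lists did without the 7 pairs, PPARA targets among them. Because those pairs were picked for arrays unlike others of their line, removing them tends to lower the spread within lines. The larger number of lists therefore cannot decide whether lines differ. Of 2 correlations between lists, 0 passed when each list came from other strain pairs and 0 without the 7 pairs, while with centred arrays 1 other relation passed (the integrated stress response with the cell cycle) and with the axis held fixed 3 did. Where no construction is named, the cause was not tested.

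With the study pair as a replicate block, 3067 genes passed in the mean over lines, and 16 lists, adding NRF2 targets and gluconeogenesis. In that fit the pair and not the line was the unit, so pairs of 1 line counted as independent replicates. The larger count need not come from the pairing: 1696 genes rose and 1371 fell with the block. With line as covariate and no block, 1704 rose and 1377 fell. Without the pairing, 1034 interaction genes passed, the median per line was 22, and 6 of the 12 named interaction genes lost their call. CC035/Unc went from 0 to 1 gene, and the fits with and without pairing changed no other call of a named gene or list.

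Of the genes named for their mean change, 18 lost their call in at least 1 alternative, none of them among the 25 largest changes, and Slc10a1 and S100a9 gained one. Besides genes marked above, Hsd3b5, Aacs, Slco1a1, Dusp1 and Nr0b2 were among the 18, each losing its call without at least 1 strain pair number. Signal over background was not used here, so it is unknown which dim probe sets measured no transcript.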

Other observations

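Several genes with the largest mean changes also differed between lines in how far they responded; those given here were singled out after their values were seen. Pctp rose in all 44 lines, yet from 0.11 in CC010/GeniUnc to 2.37 in CC037/TauUnc, and its interaction had a limma adjusted p of 1.3e-09. Vnn1 ranged from -0.24 in CC019/TauUnc to 2.41 in CC015/Unc (5.1e-04) and Gstt2 from -0.09 in CC025/GeniUnc to 1.39 in CC022/GeniUnc (1.4e-04). Ehhadh ranged from 0.05 in CC019/TauUnc to 1.72 in CC059/TauUnc (limma adjusted p = 0.00442). With arrays as deposited, CC019/TauUnc was the lowest line for Acot1, Ehhadh and the mean of the PPARA targets. By contrast the fall of Dio1, from -2.77 in CC060/Unc to -0.21 in CC033/GeniUnc, did not pass the test of a difference between lines (adjusted p = 0.0754). The ends near 0 rest on single pairs: Pctp in CC010/GeniUnc was at -0.18 without study pair 157, Gstt2 in CC025/GeniUnc at 0.10 without pair 113, Dio1 in CC033/GeniUnc at 0.01 without pair 121, Acaa1b in CC052/GeniUnc at -0.16 without pair 134, and in CC019/TauUnc Vnn1 was at -0.04 and Ehhadh at -0.09 without pair 59.

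Of the 23 genes that changed at least 1.5-fold in the mean over lines, 14 also passed the interaction test.

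In 5 of the 7 pairs with a poorly correlated TAK-875 array (0.858 to 0.905), PPARA targets and the circadian clock list rose strongly together, a feature noticed after the values were seen. Their PPARA and clock means were 1.37 and 1.04 in study pair 21, 1.26 and 1.07 in pair 108, 1.07 and 1.29 in pair 164, 1.13 and 1.17 in pair 176, and 1.13 and 0.97 in pair 178. The proteasome mean was below 0 in 4 of them (-0.33, -0.17, -0.21 and -0.44) and at 0.15 in pair 178. The 5 pairs belong to 5 lines, and the other 2 poorly correlated arrays, both of CC010/GeniUnc, had PPARA means of 0.40 and -0.32.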
